A study of Danio rerio with 48 samples.

How the data were processed

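Whole adult zebrafish were frozen and ground after 24 h of exposure, and total RNA was purified, pooled and labelled with the dye Cy3 by Agilent's one-colour amplification kit, per the labels' protocols. The deposited table holds log2 intensity values, 1 row per probe and 1 column per array. The scanner, the background correction, the normalization and their software are not given in the sources used here. The log2 scale was read from the values. The 48 columns have nearly the same distribution, with medians between 5.62 and 5.66, and are not centred per probe, so they were taken as already made comparable across arrays and no further normalization was applied. Scanner files were not used here.

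Groups and replicate numbers came from the sample labels, and columns were matched to samples through the labels. The table has 43714 probes with transcript IDs, 41681 from Ensembl and 2033 from Vega, and 61 rows of control spots, which were left out of the tests. The ID up to its suffix was taken as the transcript, and the meaning of the suffixes is not given in the sources used here. Of 21903 transcripts, 21811 had several probes. Of the control spots that should be dark, 99.7% of the values lay at or below log2 5, which was chosen after seeing the data as the background limit; 4031 probes lay at or below it on all 48 arrays and were kept in the tests.

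The analysis used R 4.3.3 with limma 3.58.1. For each metal, lmFit and eBayes were run on its 16 arrays with a coefficient per group, and contrasts compared each exposure with control and high with low. Differences between metals in the high-dose effect came from a fit of all 48 arrays. The control arrays labelled for nickel and for chromium were compared in a fit of those 8 arrays. P-values were adjusted by Benjamini-Hochberg over all 43714 probes within each contrast, with a threshold of 0.05, and no limit on fold change. Counts are counts of probes. The root mean square effect is that of all fold changes after subtraction of their expected sampling variance.

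Replicate numbers were checked for pairing by correlating deviations from group means over probes with a mean above log2 6. Within metals, same-numbered arrays correlated between -0.132 and 0.233. Out of 4 numbers, 7, 4 and 10 of 16 nickel, chromium and cobalt arrays correlated best with their own. Whether the numbers pair arrays is therefore not settled, and the main fits did not use them. For the shared controls the titles pair the arrays by pool, and the correlations of the 4 pairs were 0.554, 0.468, 0.507 and 0.614, so the value with the pool as a block is given beside the unblocked one for the comparison of these arrays and for the difference between nickel and chromium.

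Comparisons against the same controls were set against 100 simulations of unchanged groups, made by adding random combinations of each group's residual arrays to the control mean, with the 2 arrays of a shared pool receiving the same weights. The overlap of independent lists was computed per direction from the calls of each comparison. Control arrays were also divided 2 against 2, in 6 ways.

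Nothing given here pairs the transcript IDs with gene symbols, so 0 probes could be named. The 37 gene lists fixed beforehand and their set tests were therefore not run. Probes named in the text follow the fallback of a rule fixed before the data were examined: the probe with the highest mean of each transcript, and per comparison of high with control the 2 largest increases and 2 largest decreases past the threshold whose exposed arrays all lie on the same side of all control arrays. The set of 247 probes that fell over 4-fold at low chromium was chosen after the values were seen, as was its test with divided pools.

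The fit was tested on simulated data with 67, 67 and 66 of 43714 probes changed 1.5-fold, 2-fold and 4-fold, all with a mean above log2 6. In the comparison of high nickel with control it recovered 52.2%, 82.1% and 100% of them, with 7 false calls among 163. For high chromium it recovered 44.8%, 77.6% and 100%, with 16 false calls among 164, and for high cobalt 17.9%, 58.2% and 97.0%, with 13 among 128. Noise was drawn independently for each probe here, whereas the simulations of unchanged groups kept the correlation between probes. Those simulations reached 12045 calls at mid cobalt, so the false calls given here do not describe correlated probes. Recovery was not tested for dimmer probes.

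Alternatives fixed before the data were examined were leaving out the dimmest 25% of probes, quantile normalization or median centring of the arrays in the fit, the replicate number as a block, eBayes with an intensity trend and robust priors, array weights, all 48 arrays in a single fit, averaged arrays of the shared pools, a limit of 2-fold, and leaving out each replicate. Scaling to 9 control rows, taken as spike-ins from their names, whose means lay between log2 6 and 15, the control pool as a random block, and leaving out replicates for the overlap of the 3 metals and for named probes in the other metals and in the differences between metals were added after seeing the data. So was a lower bound for 3 probes, in which exposed arrays below log2 5 were set to that limit. In the spike-in scaling, each array was shifted by its mean over those rows, centred within its metal. Figures were drawn with matplotlib.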

Results

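Adult zebrafish were exposed for 24 h to nickel, chromium or cobalt dissolved in flowing tank water, and RNA from whole fish was pooled and hybridised to one-colour arrays. The series holds 48 arrays in 12 groups of 4, with a control, a low, a mid and a high exposure for each metal. Measured concentrations were 42.4, 51.0 and 64.0 mg/L for nickel, 56.5, 69.9 and 80.6 mg/L for chromium, and 39.7, 46.3 and 59.5 mg/L for cobalt. The controls of nickel and chromium were the same 4 pools, each carried by a nickel-labelled and a chromium-labelled array, while cobalt had its own 4 control arrays. The array measured 43714 probes of 21903 transcripts. Between 66.2% and 68.5% of the probes lay above a log2 intensity of 5 on each array, and the number of arrays limits the precision of a group mean. Because the files do not pair the transcript IDs with gene names, probes are given by ID. The labels do not say how many fish made up a pool or whether replicates came from separate tanks, so p-values measure the spread between these pools and arrays.

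The arrays lay apart by metal, controls included, and by exposure. Over 19421 probes with a mean above log2 6, the first principal component held 27.3% of the variance and the second 23.6%. Chromium-exposed arrays averaged 42.9 ± 0.508 (SD, n = 4) on the first component at the low dose, against -42.6 ± 1.70 (SD, n = 4) for low cobalt and 0.354 ± 3.27 (SD, n = 4) for low nickel. Controls were apart on it too, at -24.8 ± 2.23 for cobalt, 6.05 ± 2.43 for the nickel-labelled and 14.6 ± 2.48 for the chromium-labelled arrays (SD, n = 4 each). On the second component the exposed groups all lay below their controls, by the group means: nickel went from 48.3 ± 3.44 in controls to 10.9 ± 2.59 at the high dose, chromium from 45.5 ± 3.10 to -34.2 ± 13.2 and cobalt from 21.5 ± 7.86 to -36.3 ± 5.31 (SD, n = 4 each). Within groups, pairs of arrays correlated between 0.966 and 0.990 across probes, and no pair held identical values.

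**Figure D1:**
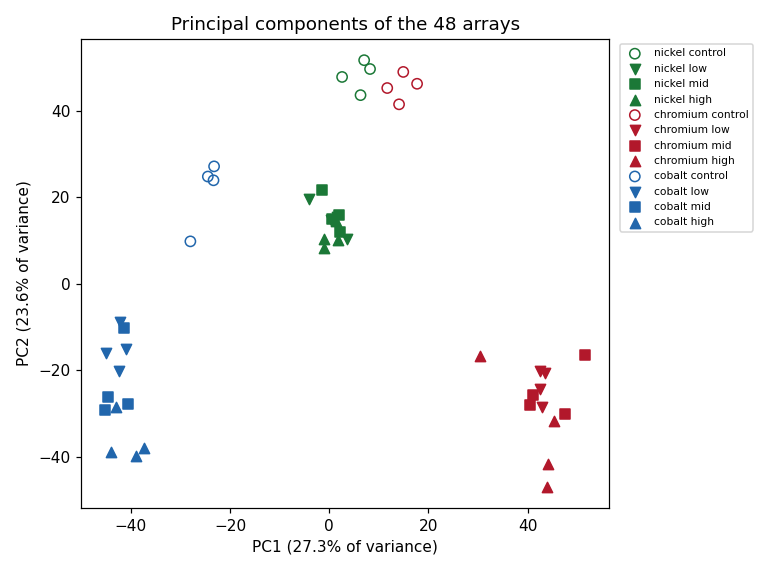
Principal components 1 (x axis, 27.3% of the variance) and 2 (y axis, 23.6%) of the 48 arrays, with colour for the metal and symbol for the exposure (open circles are controls). Chromium-exposed arrays sit at the right, cobalt arrays at the left and nickel-exposed arrays between them.

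The nickel arrays were used to ask which transcripts changed with nickel and at which concentration. At 64.0 mg/L, ENSDART00000015991_2 rose from a log2 intensity of 5.49 ± 0.16 to 10.35 ± 0.20 (SD, n = 4 each), a log2 fold change of 4.86 ± 0.31 (SE) or 29.0-fold, with a limma adjusted p of 2.9e-07. ENSDART00000055287_2 rose from 8.99 ± 0.62 to 13.12 ± 0.20, a log2 fold change of 4.13 ± 0.26 (SE), adjusted p 2.56e-07. The probes with the steepest decline under the naming rule were OTTDART00000016879_y_1, at -2.21 ± 0.30 (SE) with adjusted p 0.000261, and ENSDART00000062587_2, an abundant transcript that went from 13.61 ± 0.37 to 11.75 ± 0.18 (SD, n = 4 each), adjusted p 2.16e-05. The other probe of each of these 4 transcripts changed in the same direction and passed the threshold.

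In all, 4552 probes passed the limma threshold at high nickel, 2529 higher and 2023 lower. Low nickel gave 4213 (2197 higher, 2016 lower) and mid nickel 3299 (1876 higher, 1423 lower). Most changes were small: the median log2 change among higher calls at the high dose was 0.62, and 390 higher and 161 lower calls reached 2-fold. Of the 3150 transcripts with several probes and at least 1 call at high nickel, 1396 had all of their probes called in the same direction and 0 had probes called in opposite directions. When arrays were scaled to the spike-in control spots, the share of higher calls went from 52.1% to 67.9% at the low dose, from 56.9% to 92.0% at mid and from 55.6% to 90.4% at high, and the low-dose count became 2419. That scaling shifted the median of all probes by 0.07, 0.20 and 0.21 log2 units at low, mid and high nickel, and changes are given here relative to the deposited scaling.

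The largest decreases of the series, by log2 fold change against control, were in chromium. At 80.6 mg/L, ENSDART00000018409_2 went from 14.53 ± 0.14 to 6.56 ± 3.15 (SD, n = 4 each), a log2 fold change of -7.97 ± 1.06 (SE), adjusted p 7.24e-05. ENSDART00000067818_1 went from 13.69 ± 0.17 to 6.07 ± 2.55 (SD, n = 4 each), a log2 fold change of -7.62 ± 0.85 (SE), adjusted p 1.47e-05. With arrays at or below the background limit of log2 5 set to it, these probes were already lower by at least 8.96 and 8.47 log2 units at the low dose. The large SD at the high dose came from replicate 3, at 11.28 and 9.89, while the other 3 high arrays lay between 4.79 and 5.26 for the former and between 4.66 and 5.00 for the latter, near the background limit, with 2 arrays of each probe at or below it. With all 4 arrays and that limit, the levels were lower by at least 7.90 and 7.46 log2 units. Without replicate 3 the high-dose levels were lower by at least 9.45 and 8.69 log2 units, with the same limit. Among increases, ENSDART00000105448_x_1 rose by a log2 fold change of 5.15 ± 0.48 (SE), from 7.78 ± 1.05 to 12.92 ± 0.47 (SD, n = 4 each), adjusted p 3.12e-06. ENSDART00000105445_y_2 rose by 5.11 ± 0.48 (SE), adjusted p 3e-06. Its means, 7.77 in controls and 12.88 at the high dose, were close to those of ENSDART00000105448_x_1, so the 2 may not be separate increases. The other probes of these 4 transcripts again moved the same way and passed.

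**Figure D2:**
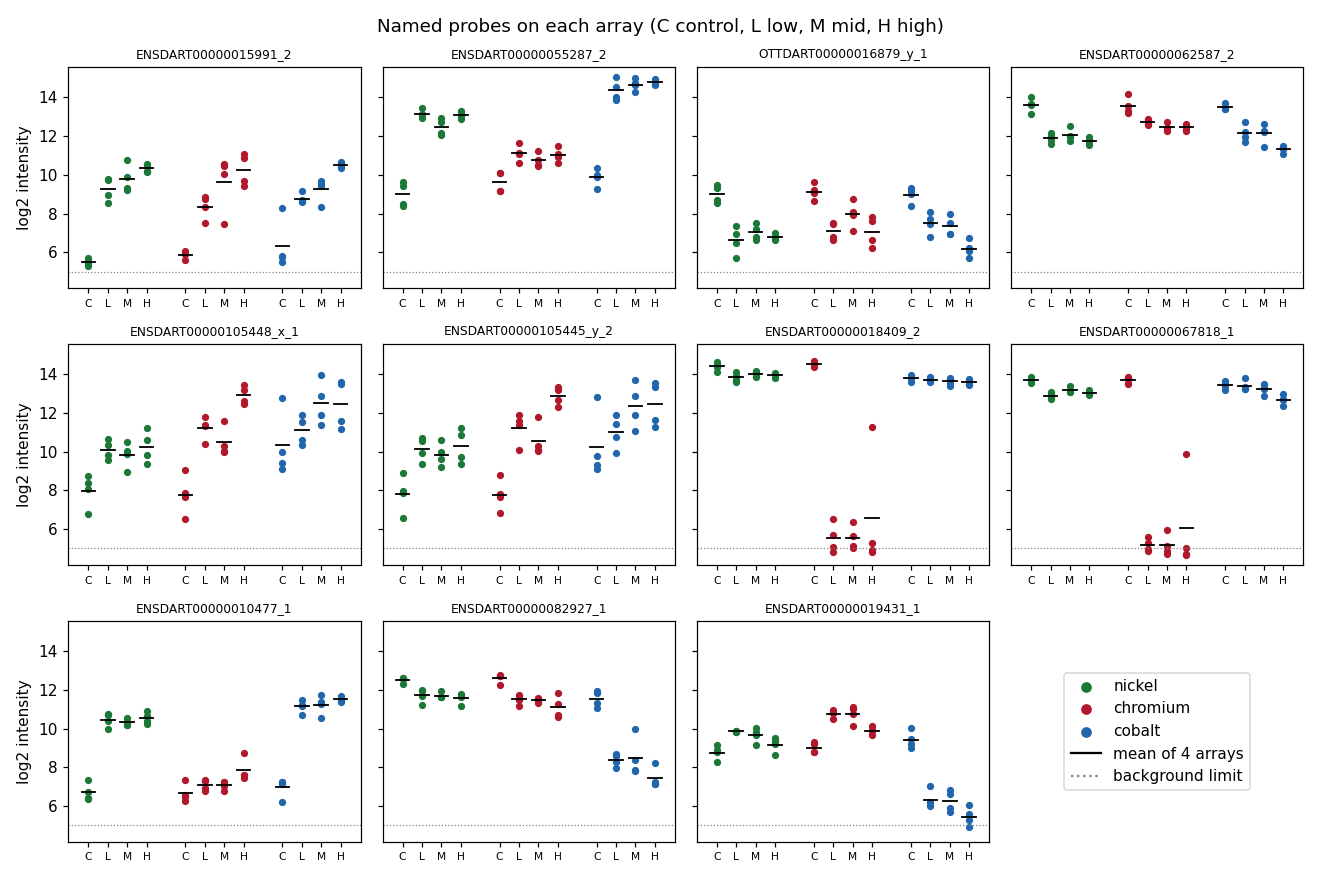
Log2 intensity (y axis) of the 11 named probes on each of the 48 arrays, by metal and exposure (x axis). Points are arrays, black bars are means of 4 arrays and the dotted line is the background limit of log2 5; in ENSDART00000018409_2 chromium high replicate 3 stands at 11.28 while the other high chromium arrays lie between 4.79 and 5.26.

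High chromium passed 7404 probes, 4020 higher and 3384 lower. Low chromium gave 4927 (2484 higher, 2443 lower) and mid chromium 5175 (2762 higher, 2413 lower). Without high replicate 3, the high-dose count was 7314. Large changes ran downward: at the low dose 949 lower against 248 higher calls reached 2-fold, and 247 lower against 37 higher calls reached 4-fold. With spike-in scaling, the low and mid counts became 2561 and 2805. The share of higher calls went from 50.4% to 42.3% at low, from 53.4% to 49.2% at mid and from 54.3% to 71.6% at high chromium. All probes shifted by 0.05, 0.07 and 0.18 at low, mid and high.

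The 247 probes that fell over 4-fold at low chromium formed a set, chosen after the values were seen, that was examined in every group. They belong to 149 transcripts, and their control intensities had a median of 9.53 and reached 15.59. Of these probes, 222 also fell over 4-fold at mid and 215 at high chromium. The set's median difference from the chromium-labelled controls was -2.68 ± 0.07 at low, -2.70 ± 0.09 at mid and -2.61 ± 0.50 at high chromium (SD, n = 4 each). High replicate 3 stood at -1.89, against -2.66 to -2.98 on the other 3 high arrays. In nickel the set's median log2 fold change was -0.58, -0.46 and -0.54 at low, mid and high, with 123, 98 and 119 of its probes called lower, and in cobalt it was -0.31, -0.38 and -0.60, with 54, 69 and 123 called lower. Tests of the difference between high-dose effects share the chromium controls with this choice of probes, so the set was also picked against 2 of the shared pools and tested against the other 2, in 6 ways. In the median division, 77.4% of such a set differed upward in nickel from chromium and 74.7% in cobalt from chromium, against 1.38% and 2.05% of all probes.

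**Figure D3:**
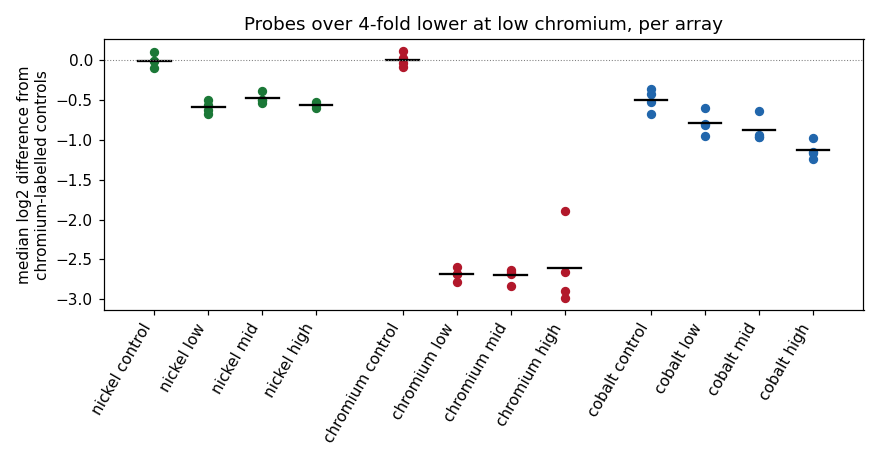
Median log2 difference from the mean of the chromium-labelled controls (y axis) over the 247 probes that fell over 4-fold at low chromium, on each array by group (x axis); black bars are group means. The chromium-exposed arrays lie between -1.89 and -2.98, and high replicate 3 is the uppermost of them.

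Cobalt at 59.5 mg/L raised ENSDART00000055287_2 from 9.87 ± 0.44 to 14.79 ± 0.13 (SD, n = 4 each), a log2 fold change of 4.93 ± 0.25 (SE), adjusted p 1.87e-08. The other probe of that transcript gave a log2 fold change of 6.23. ENSDART00000010477_1 rose by a log2 fold change of 4.55 ± 0.26 (SE), from 6.96 ± 0.50 to 11.50 ± 0.11, adjusted p 5.84e-08. Both named decreases were of probes well above background in controls: ENSDART00000082927_1 went from 11.53 ± 0.40 to 7.43 ± 0.52 (SD, n = 4 each), a log2 fold change of -4.09 ± 0.41 (SE), adjusted p 1.11e-05, and ENSDART00000019431_1 went from 9.43 ± 0.45 to 5.44 ± 0.47, a log2 fold change of -3.99 ± 0.32 (SE), adjusted p 1.55e-06; 1 of its 4 high arrays lay below the background limit, at 4.92, and with that array at the limit the decrease is at least 3.97 log2 units. The same 2 directions held for the other probe of each transcript, past the threshold.

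High cobalt passed 5846 probes, 2987 higher and 2859 lower. Low cobalt gave 2840 (1619 higher, 1221 lower) and mid cobalt 3556 (1916 higher, 1640 lower). With spike-in scaling, the share of higher calls went from 57.0% to 76.3% at low, from 53.9% to 77.4% at mid and from 51.1% to 94.8% at high cobalt, where 21957 probes passed and the median of all probes shifted by 0.34. The mean level of the spike-in spots was 8.58 ± 0.07 at high cobalt against 8.92 ± 0.06 in cobalt controls (SD, n = 4 each), a difference of -0.34 with a 2-sided exact permutation p of 0.0286, the smallest this design allows, and 0.257 after Benjamini-Hochberg over the 9 comparisons against control.

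**Figure D4:**
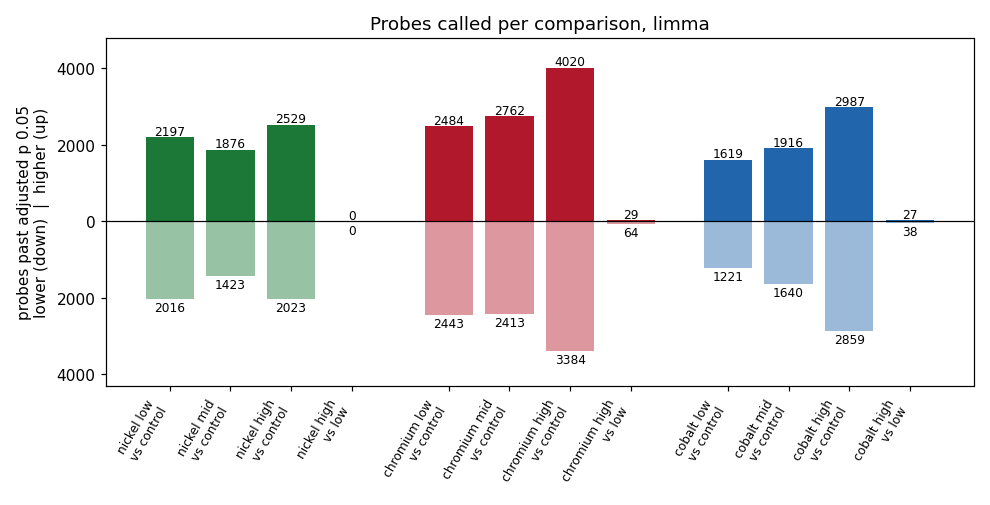
Number of probes past a limma adjusted p threshold of 0.05 (y axis) in each comparison (x axis), with higher calls above 0 and lower calls below it. Counts against control run from 2840 at low cobalt to 7404 at high chromium, and comparisons of high with low run from 0 to 93.

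Within each metal, high exposures were set against low ones to ask whether the response depended on concentration. In nickel 0 probes passed limma's test, with 3186 at an unadjusted p under 0.05; the test with an intensity trend and the fit of all 48 arrays each passed 1. In chromium 93 passed (29 higher, 64 lower) and in cobalt 65 (27 higher, 38 lower). These counts were unstable. The chromium count ran from 1 without high replicate 4 to 187 without high replicate 3, and was 5, 41, 4 and 19 without low replicates 1, 2, 3 and 4 and 3 without high replicate 1. The cobalt count ran from 0 without high replicate 1 to 293 without high replicate 4, and was 7, 4, 15 and 110 without low replicates 1, 2, 3 and 4 and 20 without high replicate 2. Spike-in scaling gave 155 in chromium, 72.3% of them higher against 31.2%, and 722 in cobalt, 95.6% higher against 41.5%. After removal of array spread, the root mean square effect against control was 0.260, 0.232 and 0.269 log2 units at low, mid and high nickel, 0.385, 0.390 and 0.427 for chromium and 0.271, 0.298 and 0.370 for cobalt.

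Doses of a metal shared their calls, and also their control arrays. Low and high nickel had 2983 probes called in the same direction and 0 in opposite ones, where independent lists would share 127 higher and 93.3 lower probes. In 100 simulations of unchanged groups against the same controls the overlap averaged 1.64 probes. The median number of simulated calls was 0 in each comparison, so low simulated overlaps follow from few calls. They do not show what shared controls add among real calls. With the control arrays divided between the doses the median overlap was 1352. Each comparison then kept only 2 control arrays and less power, so the fall does not measure shared controls alone. For chromium the overlap was 4210, with a simulated mean of 5.06 and a median of 2503.5 with divided controls. For cobalt it was 2455, with a simulated mean of 51.5, a highest simulated value of 3963 and a median of 1192 with divided controls. The correlation of low-dose and high-dose fold changes across probes was 0.836 in nickel, 0.907 in chromium and 0.827 in cobalt, against simulated values of 0.466, 0.499 and 0.416. The covariances were 0.0778, 0.169 and 0.108, against 0.0113, 0.0105 and 0.0124 in the simulations. With divided controls the median covariances were 0.0663, 0.158 and 0.0959.

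Across metals, 1894 probes of 1310 transcripts were called in the same direction at all 3 high doses, 1199 higher and 695 lower. Independent lists would share 26.1 in all. No draw of 100 simulations of unchanged groups gave any, so the highest simulated value was 0. With a median of 0 simulated calls per comparison, such draws could hardly overlap, so that value is no benchmark for real calls. The median with the shared control pools divided between nickel and chromium was 1129. Nickel and chromium then kept 2 control arrays each and less power, so the fall does not measure shared controls alone. With spike-in scaling, 93.2% of these calls were higher against 63.3%. ENSDART00000015991_2 was among them, at 4.41 ± 0.58 (SE) in chromium, adjusted p 6.4e-05, and 4.22 ± 0.48 (SE) in cobalt, adjusted p 3.79e-05. In cobalt, control replicate 2 stood at 8.26 against 5.47 to 5.78 on the other 3 controls, and without it the log2 fold change was 4.87, adjusted p 9.24e-08. High nickel and high chromium shared 1698 higher and 1120 lower probes, where independent lists would share 233 and 157. With the same limits, the simulated mean overlap was 0.09 and the median with divided pools 1497.5. Their fold changes correlated at 0.595 across probes against 0.214 in the simulations, and their covariance was 0.0831 against 0.00479. With divided pools the median covariance was 0.0789. High nickel and high cobalt, with separate controls, shared 1452 higher and 1015 lower probes, where independent lists would share 173 and 132. High chromium and high cobalt shared 1865 and 1286, where independent lists would share 275 and 221.

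Tests of the difference between high-dose effects asked which probes responded differently to the metals as exposed, at unequal concentrations. Nickel and chromium differed at 1237 probes (934 with the larger value in nickel, 303 in chromium), cobalt and nickel at 994 (515 larger in cobalt, 479 in nickel) and cobalt and chromium at 1841 (1089 larger in cobalt, 752 in chromium). With the control pool as a random block, an alternative added after seeing the data, nickel and chromium differed at 1722 probes (1186 larger in nickel, 536 in chromium). ENSDART00000018409_2 differed by 7.54 ± 0.93 (SE) between nickel and chromium, limma adjusted p 3.26e-07, which with 2 of the 4 high chromium arrays at the background limit is at least 7.47, and without chromium high replicate 3 at least 9.02. ENSDART00000055287_2 rose more in nickel than in chromium, by 2.73 ± 0.39 (SE), adjusted p 5.22e-06, and more in cobalt than in chromium, by 3.53 ± 0.39 (SE), adjusted p 1.88e-08. ENSDART00000010477_1 gave the same order, with differences of 2.63 and 3.35. ENSDART00000019431_1, lower in cobalt, was called higher in chromium at 0.88 ± 0.19 (SE), adjusted p 0.0043, and the effects differed by -4.86 ± 0.37 (SE), adjusted p 3.07e-12, or by at least 4.84 in size with the cobalt array below the background limit set to it. ENSDART00000082927_1 fell more in cobalt than in nickel, by a difference of -3.14 ± 0.42 (SE), adjusted p 6.04e-06. Called against control and different from both other metals were 50 higher and 565 lower probes in chromium, 162 higher and 196 lower in cobalt, and 29 higher and 30 lower in nickel. With the arrays of each shared pool averaged, the controls of nickel and chromium cancel and their difference rested on the exposed arrays alone, at 4153 probes (2069 larger in nickel, 2084 in chromium). That contrast no longer removes differences between the nickel and chromium array sets, so its count is not comparable with 1237. Spike-in scaling gave 760, 390 and 1225 probes for the nickel-chromium, cobalt-nickel and cobalt-chromium differences, and the split between larger values in the former and in the latter metal became 703 and 57, 264 and 126, and 1021 and 204.

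The nickel-labelled and chromium-labelled arrays of the shared controls carried the same pools and measured how far arrays alone differ. With 4 arrays on each side, 177 probes passed limma's test, 17 higher and 160 lower on the nickel-labelled arrays. With the pool as a block, 496 passed, 75 higher and 421 lower. Leaving out an array gave 106, 75, 95 and 85 without nickel-labelled replicates 1, 2, 3 and 4, and 100, 82 and 80 without chromium-labelled replicates 2, 3 and 4. The largest difference was -2.10 log2 units.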

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

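The tests of single-probe faults, of a common proportion, of chance in the spike-in levels, of spread and concentration range in nickel, and of the splits that exchange equal numbers of arrays were chosen after the results they bear on were seen, as were spike-in scaling and the leaving out of arrays for differences of named probes.

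In chromium high replicate 3, ENSDART00000018409_2 at 11.28 and ENSDART00000067818_1 at 9.89 lay far above the other 3 arrays of the group. They belong to the set that fell over 4-fold in chromium-exposed fish. The kept share was the array's excess over the low chromium mean, as a percent of the control's excess, on the linear scale. Over the 36 probes that fell over 16-fold, this array had a median kept share of 12.5%, with a range of 5.32% to 36.2%. For the decrease at low chromium, faults of single probes are argued against, since in 97.3% of the transcripts with several probes every probe was called lower there. That share does not bear on the values of high replicate 3. Control-like RNA mixed into this array alone is argued against as the whole cause: probes that rose over 4-fold at mid chromium reached 0.614 of the rise in the other 3 high arrays (quartiles 0.476 and 0.809), where the kept share predicts 0.875 and the other arrays ranged from 0.877 to 1.18; with probes picked from the other 3 high arrays instead, as first worded, the share was 0.639. Loss of an unnamed tissue part in a common proportion stays open, as a hypothesis: in this array the log2 kept share varied 1.80 times as much between transcripts (SD 0.66) as within them (SD 0.36, permutation p 0.0003), between the bounds set for either answer, and the decreases at low chromium spanned 15.9-fold, which other tissues' own expression of a transcript allows. A weaker response of this pool to chromium, a difference in the makeup of the pools and an effect of chromium on the transcripts themselves also stay open and were not tested.

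The mean level of the spike-in spots was lower than in controls in all 9 exposed groups. Whether the normalization sets the direction of calls stays open. With spike-in scaling the share of higher calls moved by up to 43.7 percentage points, at high cobalt, and 0 calls reversed, but a shift of whole arrays by these same spots largely sets both values, so neither decides it. Chance among the arrays of a metal cannot be told apart from an effect, since exact permutation p of high against control was 0.171 in nickel, 0.343 in chromium and 0.0286 in cobalt, with 4 arrays on each side. No biological explanation was tested.

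No probe passed the comparison of high with low nickel, the third pattern, with a count of 0. A larger spread of the nickel arrays is argued against as the whole cause. In the fit of each metal, the median SE of high against low was 0.116 in nickel, 0.114 in chromium and 0.130 in cobalt. In a fit of all 48 arrays, where the metals share their residual variance, nickel gave 0 to 2 probes with each low or high array left out. Chromium gave 34 to 334 there. Cobalt gave 402 to 1219, but a shared variance can be too small for its arrays, so that range is not a fair comparison. A narrower range of concentrations is argued against too, as the ratio of high to low was 1.51 in nickel and 1.43 in chromium, which had calls. The steps from low to high differed between nickel and cobalt at 38 probes and between nickel and chromium at 0, so a lack of any difference between metals is argued against for cobalt only. A response to nickel that is already near its limit at 42.4 mg/L stays open and was not tested.

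The effects at the high dose differed between nickel and chromium at 1237 probes, between cobalt and nickel at 994 and between cobalt and chromium at 1841. When control and high arrays were exchanged between metals at random, 5, 6 and 6 of 100 splits, the real ones included, gave counts as large, so this test does not exclude chance; the highest other counts were 3942, 6065 and 7361. All 4, 5 and 5 such other splits exchanged unequal numbers of control and high arrays, differing by 2 or more, which turns the difference between the metals' arrays into part of the contrast and points to a structure of the samples. Among 100 splits that exchanged equal numbers, only the real one gave as many in each comparison (1, 1 and 1), and the highest others were 11, 4 and 81. Such splits place arrays of both metals in a group, which widens the spread within groups. Low counts follow from that, so these splits do not exclude chance either.

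Named probes whose effect differed between metals were, for nickel minus chromium, ENSDART00000055287_2 (2.73), ENSDART00000018409_2 (7.54), ENSDART00000067818_1 (6.97) and ENSDART00000010477_1 (2.63). For cobalt minus chromium they were ENSDART00000055287_2 (3.53), ENSDART00000062587_2 (-1.06), ENSDART00000105448_x_1 (-3.01), ENSDART00000018409_2 (7.78), ENSDART00000067818_1 (6.85), ENSDART00000010477_1 (3.35), ENSDART00000082927_1 (-2.59) and ENSDART00000019431_1 (-4.86). For cobalt minus nickel they were ENSDART00000082927_1 (-3.14) and ENSDART00000019431_1 (-4.39). With each of 16 arrays left out in turn, ENSDART00000105448_x_1 lost its call in 10 cases, with a difference of -2.19 and a limma adjusted p of 0.16 without cobalt control replicate 2, and ENSDART00000062587_2 lost it in 6, with adjusted p up to 0.0907. With exposed arrays below log2 5 set to that limit, ENSDART00000018409_2 and ENSDART00000067818_1 differed by at least 7.47 and 6.81 for nickel minus chromium and 7.71 and 6.69 for cobalt minus chromium. Without chromium high replicate 3 these bounds were 9.02 and 8.04, and 9.26 and 7.92. With the same limit, ENSDART00000019431_1 differed by at least 4.84 in size for cobalt minus chromium and 4.37 for cobalt minus nickel. The other differences kept their call and direction in every case.

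Of 84 groups of 4 arrays examined, 9 held a value far from the others, where chance gives about 1 in 20. Besides the 2 above, ENSDART00000105445_y_2 stood at 11.79 in chromium mid replicate 4 against 10.04 on the lowest array of its group. ENSDART00000010477_1 stood at 6.21 in cobalt control replicate 4 against 7.13 to 7.24. ENSDART00000082927_1 stood at 8.21 in cobalt high replicate 4 against 7.12 to 7.25. The spike-in mean was 11.75 in chromium mid replicate 2 against 11.31 to 11.34. The negative control spot was 5.99 in chromium low replicate 1 against 4.68 to 4.71, and 4.68 in cobalt control replicate 1 against 4.74 to 4.74. The median of the set that fell in chromium was -0.64 in cobalt mid replicate 3 against -0.96 to -0.94.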

How the results depend on the processing

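Quantile normalization and median centring kept all 17 counts within 1.5 times their value. The deposited columns already had nearly the same distribution, so these settings could change little and do not test the normalization. Over all settings, 212 log2 fold changes of named probes were recomputed in the comparison each was named for. None lost its call or direction, the highest limma adjusted p being 0.00142. These probes were picked for the largest separated changes in the same comparisons. Keeping their calls was thus largely fixed in advance and says nothing of other probes. Without the dimmest 25% of probes, high against low gave 162 in chromium and 176 in cobalt, where fewer probes were tested. The replicate block gave 16 and 111 for these, and 496 for the shared controls, and it moved no other count by over 1.5 times; as a hint from the data only, 7, 4 and 10 of 16 nickel, chromium and cobalt arrays correlated best with their own number. With an intensity trend, high against low gave 1, 192 and 293 in nickel, chromium and cobalt; array weights gave 227 in chromium and 109 in cobalt; all 48 arrays in a single fit gave 1, 202 and 832; the cause was not tested. Averaging the shared pools gave 4153 for nickel minus chromium, where the controls cancel and differences between array sets stay in, so it is not comparable with the main count. With a limit of 2-fold, low, mid and high gave 485, 362 and 551 in nickel, 1197, 1264 and 1684 in chromium and 605, 739 and 1333 in cobalt, by construction fewer. Spike-in scaling, added after seeing the data, gave 2419 at low nickel, 2561 and 2805 at low and mid chromium, 21957 at high cobalt, 3, 155 and 722 for high against low, and 760, 390 and 1225 for nickel minus chromium, cobalt minus nickel and cobalt minus chromium. Leaving out a replicate gave 1 to 187 for high against low chromium, 0 to 293 for cobalt and 75 to 121 for the shared controls; the other 14 counts stayed within 1.5 times. The gene list tests were not run, for lack of gene names. Probes near log2 5 limit what can be read of low levels.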

Other observations

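Hypotheses are not offered here beyond the tests given, and the values below were chosen after seeing the data. Some probes answered to the metals in opposite directions. Among high-dose calls, 50 probes went opposite ways in nickel and chromium (32 higher in nickel), 32 in nickel and cobalt (12 higher in nickel) and 89 in chromium and cobalt (45 higher in chromium). Independent lists would hold 382, 304 and 494 such probes. Nickel and chromium shared their control pools, and their fold changes correlated at 0.214 in simulations of unchanged groups. Independent lists are therefore not a fair baseline for the 50 probes of that pair. ENSDART00000019431_1, lower at high cobalt and higher at high chromium, is one of the 89.

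After removal of array spread and of the covariance from the shared pools, the high-dose effects of cobalt and nickel correlated at 0.794 across probes (0.780 to 0.810 with each array left out), those of nickel and chromium at 0.680 (0.666 to 0.695) and those of cobalt and chromium at 0.647 (0.637 to 0.662). Without the 247 probes that fell over 4-fold at low chromium the values were 0.795, 0.728 and 0.702. Probes are not independent replicates, and the order was not tested beyond leaving out arrays.

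Cobalt controls differed from the nickel-labelled controls at 5326 probes and from the chromium-labelled ones at 6957, while the nickel-labelled and chromium-labelled arrays of the same pools differed at 450 in the same fit of 48 arrays. The spike-in mean of cobalt controls was lower than that of nickel-labelled controls by a difference of -2.37. Fish, pools and array runs of cobalt cannot be separated by the labels. ENSDART00000105448_x_1 stood at 10.32 ± 1.68 (SD, n = 4) in cobalt controls, with replicate 2 at 12.79 against 9.10 to 9.97 on the others. Its log2 fold change there at the high dose, 2.14 ± 0.81 (SE), did not pass limma's test, adjusted p 0.106, while without that array it was 2.96 with adjusted p 0.0102, and with each of the 8 arrays left out adjusted p ran from 0.0102 to 0.265.

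Regrouping the arrays gave no other count against control as large as the real one. The smallest share this test allows is 2.86%. The other splits mix exposed and control arrays, which widens the spread within groups. Their low counts therefore do not measure what unchanged groups would give. Of 35 splits of the 8 arrays of each comparison, only the real one (1 in each) gave as many calls: the highest other counts were 3, 2 and 1 for low, mid and high nickel beside 4213, 3299 and 4552, then 2, 1 and 1 for chromium beside 4927, 5175 and 7404, and 1, 54 and 9 for cobalt beside 2840, 3556 and 5846. For high against low the highest others were 2 beside 93 in chromium and 9 beside 65 in cobalt, each with 1 split as large. For nickel the real count was 0 and the highest other 2, so 35 of 35 splits gave as many and chance is not excluded. For the shared controls the highest other was 56 beside 177, with 1 split as large. Those splits do not keep the 2 arrays of a pool on opposite sides, so they ignore the pairing and do not decide on chance there. In the simulations of unchanged groups, which keep the correlation between probes, the median number of calls was 0, yet 0 to 2 of 100 draws reached the observed count, and draws rose as high as 12045 calls at mid cobalt.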
